A study of Caulobacter vibrioides with 6 samples.

How the data were processed

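RNA was sequenced from 6 cultures of Caulobacter crescentus NA1000, a laboratory strain of a stalked alphaproteobacterium. The 6 libraries fall into 3 groups of 2, namely wild type, flbD::Tn (a transposon insertion in flbD) and ΔmadA (a deletion of madA), and the labels call the 2 cultures of each group independent biological replicates. Per the labels, overnight cultures in rich medium (PYE) were restarted in 10 ml at an optical density of about 0.05 and grown at 30 °C to about 0.5. Per the labels, cells were lysed with lysozyme, RNA was column-purified with DNase treatment, ribosomal RNA was removed, libraries were made with a kit for prokaryotic RNA, and single-end reads of 50 cycles were sequenced. Per the labels, the authors checked reads with FastQC 0.72, aligned them to the NA1000 genome with Bowtie2 2.3.4.3 and counted reads per gene feature with htseq-count (HTSeq 0.9.1). The strand, overlap and multi-mapping settings of that counting are not given in the labels, so values of overlapping genes and of near-identical paralogs such as the flagellins are uncertain.

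The values used for every test are the deposited raw counts, which are whole numbers of reads per gene. The deposited normalized signal equals those raw counts divided by 1 size factor per library, which the authors took from DESeq2 (2.11.40.6 in their workflow). The deposited log2 fold changes compare each mutant with wild type and come from the authors' DESeq2 run. They lie near 0 for genes with few reads, as shrunken estimates do, but the setting is not stated, so they were used only for their sign. The deposited p-value of each comparison is unadjusted per the file headers, and it was adjusted here with the Benjamini-Hochberg method for a comparison of calls. The table holds 3886 protein-coding genes. All 3886 matched the reference gene table for the same chromosome by locus tag, with the same start and end. Coordinates below are those of coding regions on the NA1000 chromosome, and untranslated regions are not part of the table. The files give a symbol for 533 genes and the reference table raises this to 667. The symbol madA comes from the reference table, since the files name that gene a hypothetical protein.

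Library totals were 2708363 and 2002453 counts in wild type, 2280717 and 2605432 in flbD::Tn and 2951749 and 1942356 in ΔmadA, a highest-to-lowest ratio of 1.52. A floor of 3 counts corresponded to 1.02 to 1.55 CPM, the usual library-size-scaled count, across libraries. The 10 genes with the most reads held 11.3% to 12.8% of the counts. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

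Differential expression was tested in R 4.3.3 with edgeR 4.0.16. All 6 libraries entered 1 fit with genotype as the only term, so that the 3 groups shared an estimate of the spread. Counts were scaled with TMM (factors from 0.975 to 1.02), genes with few reads were removed with the default expression filter, which left 3612 genes and took out 274, and the robust quasi-likelihood F test was applied. Adjusted p-values are Benjamini-Hochberg values over the 3612 genes, from that test unless stated otherwise, and genes with an adjusted p under 0.05 are called higher or lower. The biological coefficient of variation was 0.154 and the median standard error of a log2 fold change was 0.24. Levels are TMM-scaled CPM with the standard deviation (SD) of the 2 libraries. Log2 fold changes carry a standard error (SE) implied by the F statistic of the test. It is the absolute log2 fold change divided by the square root of F.

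The 23 gene lists were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, beside an estimated correlation, and adjusted over the lists of a comparison. A list with fewer than 3 measured members was described but not tested. The lists were class II, class III and class IV flagellar genes, flagellin glycosylation, motor stators, chemotaxis, pilus, holdfast and stalk, cell division, cell cycle regulators, polarity, swarmer phase genes, cyclic di-GMP turnover, DNA replication, SOS and DNA repair, heat shock and proteolysis, general stress, ribosomal proteins, S-layer, TonB-dependent receptors, the respiratory chain with ATP synthase, prophage genes and transposases. They were drawn up from general knowledge of the organism. A gene may sit in several lists. The 61 listed names that matched no symbol were left out, though such genes may be present under another name. Among them were dnaB, dnaN, gyrA and ssb of DNA replication and groEL, groES and htpG of heat shock.

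Genes were named by a rule. It takes the 10 largest rises and 10 largest falls per mutant, and 5 and 5 between the mutants, among called genes with a mean of at least 10 CPM whose libraries did not overlap between the groups. It adds up to 4 called members of each list by size of change, and a set named whatever its values (flbD, madA, fliX, flhA, fliF, flgE, fljK, fljL, ftsZ, ftsA, ftsQ, mipZ, tipF, ctrA, sciP, gcrA, ccrM, dnaA and pilA). Genes outside the rule are said to be chosen after their values were seen. The tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative is said to have been added later. The alternatives were DESeq2 1.42.0, limma-voom, DESeq2-style size factors, library totals only, no filter, a stricter filter, only the libraries compared, a replicate block, a fold of at least 2 and leaving out each library in turn.

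Both mutants were compared with the same wild type libraries, which adds covariance without any effect. Its size was estimated from 100 simulated data sets without an effect, drawn with the fitted spread. The procedure was also tested on simulated data of this size with 100 genes each changed by 1 and by 2 on the log2 scale. It recovered 66% and 89% of them for flbD::Tn with 6 false calls among 161, and 65% and 90% for ΔmadA with 10 false calls among 165. Motility, cell division measurements and protein levels were not analysed here.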

Results

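Reads per gene were counted in 6 libraries of Caulobacter crescentus NA1000, 2 each of wild type, flbD::Tn and ΔmadA. FlbD is a response regulator that activates late flagellar genes and represses some early ones. The gene madA encodes a small protein, studied here in a series on the link between the flagellum and cell division. Totals ran from 1942356 to 2951749 counts per library. The 2 libraries of a group correlated across genes with r = 0.980 in wild type, 0.977 in flbD::Tn and 0.974 in ΔmadA on the log2 CPM scale, although genes are not independent replicates. The first principal component, 37.7% of the variance, set wild type apart from both mutants, and the second, 27.5%, set flbD::Tn apart from ΔmadA.

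Reads of madA were nearly absent from ΔmadA, while reads of flbD rose in flbD::Tn. The gene madA (CCNA_03790, positions 3955324 to 3955599, plus strand) stood at 706 ± 47.8 CPM (SD, n = 2) in wild type. Its 2 ΔmadA libraries held 3 reads together against 3354 in wild type, a ratio of 1150 with a 95% counting interval from 394 to 5580. In flbD::Tn, madA rose to 1417 ± 41.0 CPM (SD, n = 2), a log2 fold change of 1.00 (SE 0.17, adjusted p = 0.000713). The gene flbD (CCNA_00954, positions 1030701 to 1032068, plus strand) stood at 170 ± 5.37 CPM (SD, n = 2) in wild type. Its reads rose in flbD::Tn to 1234 ± 41.8 CPM (SD, n = 2), by 2.86 on the log2 scale (SE 0.19, adjusted p = 4.63e-09). Reads over an interrupted gene do not show that a full transcript or protein was made, and the position of the insertion is not known from the files. In ΔmadA, flbD stood at 220 ± 68.0 CPM (SD, n = 2) and did not pass (0.38, adjusted p = 0.25), but passed when ΔmadA replicate 2 was left out (0.65, adjusted p = 0.0129).

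**Figure D1:**
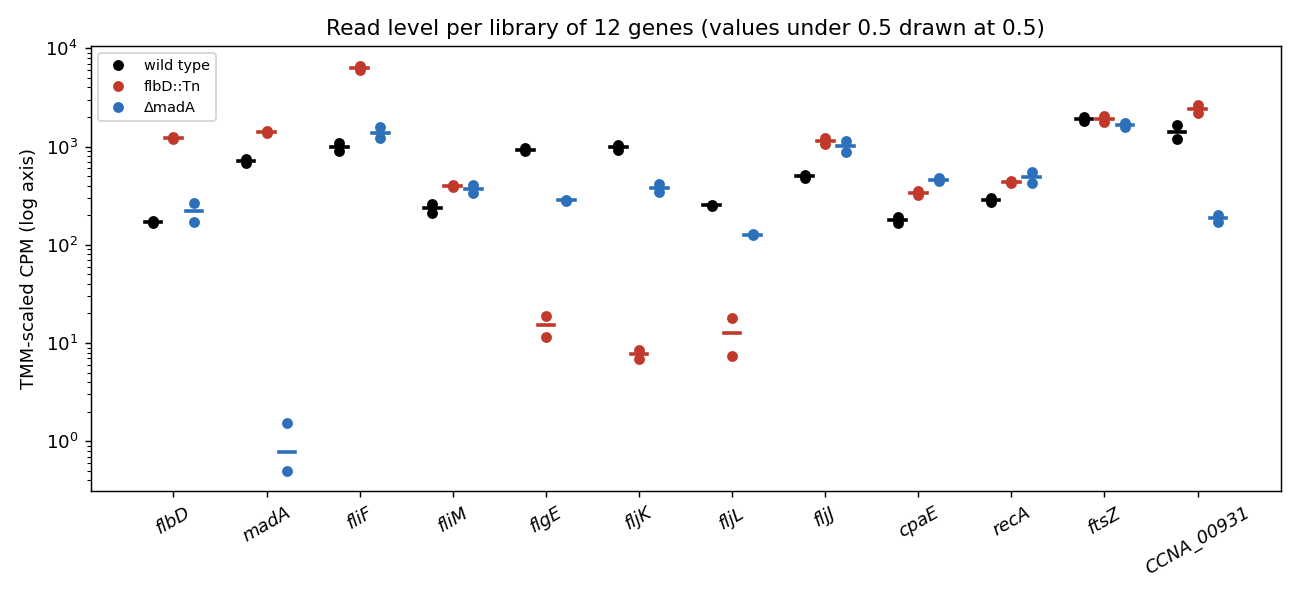
Read level in TMM-scaled CPM on a log axis for selected genes, with a point per library and a bar at the mean of the 2 libraries of each genotype. The hook gene flgE and the flagellin gene fljK were lowest in flbD::Tn (means 15.2 and 7.75 CPM), while fliF was highest there (6288 CPM) and CCNA_00931 was lowest in ΔmadA (187 CPM).

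The comparison of flbD::Tn with wild type asks which genes depend on a regulator of flagellar assembly. All 10 measured class III flagellar genes fell, and 16 of 19 class II genes rose. Transcripts of the hook protein FlgE (CCNA_00947, positions 1024495 to 1026270, plus strand) fell from 932 ± 44.2 to 15.2 ± 5.15 CPM (SD, n = 2), a log2 fold change of -5.95 (SE 0.21, adjusted p = 7.29e-14). Those of the flagellin FljK (positions 1636359 to 1637180, plus strand) fell from 979 ± 83.6 to 7.75 ± 1.15 CPM (SD, n = 2), a change of -6.98 (SE 0.22, adjusted p = 2.51e-14). In the other direction, fliF (positions 1026984 to 1028648, plus strand), which encodes the membrane ring of the basal body, rose from 996 ± 130 to 6288 ± 408 CPM (SD, n = 2), by 2.66 (SE 0.16, adjusted p = 2.72e-10).

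The class III genes (rod, rings and hook) fell in flbD::Tn, 10 of 10 over all genes and adjusted over the list alone, with a median log2 fold change of -5.06 and a range from -6.47 to -3.90. The camera adjusted p of the list was 4.82e-32, and adjusted p = 0.0702 with an estimated correlation. The largest falls were those of flgD, the hook cap scaffold (-6.47), and flgE, followed by the ring gene flgI (-5.35, adjusted p = 1.61e-09) and the rod gene flgF (-5.27, adjusted p = 1.35e-13). Among 19 class II genes (membrane ring, switch and export apparatus), 16 rose and none fell, or 18 adjusted over the list alone. Their median was 1.05 (camera adjusted p = 3.83e-29, and adjusted p = 0.0242 with an estimated correlation), and 10 rose when wild type replicate 1 or flbD::Tn replicate 1 was left out. The largest rises were in the neighbouring genes fliF, fliG (2.52), fliN (2.70) and flbD. The export gene flhA passed narrowly (0.56, adjusted p = 0.0476) and was no longer called when wild type replicate 1 (0.131) or 2 (0.423), or flbD::Tn replicate 1 (0.209) or 2 (0.189), was left out. Its call also ended with DESeq2 (0.0809), DESeq2-style size factors (0.06), a stricter filter (0.0504) or a replicate block (0.0926). The flagellar assembly regulator fliX had a log2 fold change of 1.05 and did not pass (adjusted p = 0.0768), though it passed without ΔmadA replicate 1 (adjusted p = 0.0389).

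Of 8 class IV genes (flagellins and their regulators), 4 fell and 1 rose, or 5 and 1 adjusted over the list alone (median -0.74, camera adjusted p = 7.32e-07, and adjusted p = 0.0858 with an estimated correlation). The flagellins did not move alike: fljK fell most, fljL fell by 4.33 and fljN fell by 1.73, while fljJ rose by 1.20 (adjusted p = 2.09e-05). The remaining fall was in fljM (-0.88, adjusted p = 0.000204), named after its values were seen. A gene annotated as the chemotaxis protein MotD, CCNA_00945 (positions 1022922 to 1023653), lies beside the hook genes and held 3 reads in flbD::Tn against 1893 in wild type, a ratio of 661 with a counting interval from 226 to 3210. It overlaps CCNA_00944, a hook-length gene that fell by 7.99 (adjusted p = 5.83e-10), so reads over the shared stretch are uncertain.

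Beyond the flagellum, 7 of 17 measured pilus genes rose in flbD::Tn and none fell, or 8 and 1 adjusted over the list alone (median 0.42, camera adjusted p = 0.00351, and adjusted p = 0.215 with an estimated correlation). Without wild type replicate 1 or flbD::Tn replicate 1 the rises numbered 4, and the median was 0.20 without flbD::Tn replicate 2. Examples were cpaD (1.21, adjusted p = 0.000204), cpaC (1.01) and cpaE (0.92), which encode parts of the pilus secretion system, whereas the pilin gene pilA stayed at -0.22 (adjusted p = 0.778). Of 42 chemotaxis genes 3 rose and 2 fell, or 5 and 3 adjusted over the list alone, with a median of 0.06, a mean of -0.14 and a test pointing up (camera adjusted p = 0.614). They were the receptors CCNA_02364 (1.14) and CCNA_02402 (1.10), the CheW-like gene CCNA_03120 (-1.05), CCNA_00945, and the receptor CCNA_01727 (0.84, adjusted p = 0.0017, or 0.101 without wild type replicate 1), the last named after its values were seen. The holdfast list had 1 rise and 1 fall among 24, or 2 and 1 adjusted over the list alone, hfsA (0.88) and hfsJ (-1.32, adjusted p = 4.8e-06), with a camera adjusted p of 0.974.

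Of 24 cell division genes 6 rose and none fell in flbD::Tn, also when adjusted over the list alone (median 0.10, camera adjusted p = 0.014, and adjusted p = 0.215 with an estimated correlation). The list adjusted p became 0.0697 without wild type replicate 1, where edgeR called 0 members, and 2 members were called without wild type replicate 2 or either flbD::Tn library. The median was 0.20 without flbD::Tn replicate 2. Its largest rises, mraW (1.10, adjusted p = 0.00361) and the divisome gene ftsL (1.02, adjusted p = 0.0023), were not called without wild type replicate 1 (0.12 and 0.107). The division genes ftsZ, ftsA, ftsQ and mipZ did not pass, with log2 fold changes of 0.01, 0.06, 0.28 and 0.00 (adjusted p = 0.992, 0.931, 0.636 and 0.998). None of the master regulators ctrA (0.21, adjusted p = 0.491), gcrA (-0.17, adjusted p = 0.906) or dnaA (0.26, adjusted p = 0.418) passed. The methyltransferase gene ccrM (-0.45, adjusted p = 0.0588) did not pass. It passed without ΔmadA replicate 1 (0.0327) or 2 (0.0273), with DESeq2 (0.0319), DESeq2-style size factors (0.0476) or a stricter filter (0.0493), and with only the 4 libraries compared (0.0278). Of 24 cell cycle regulators 1 fell, or 2 adjusted over the list alone (camera adjusted p = 0.811). It was sciP (-1.30, adjusted p = 0.022), which was not called without wild type replicate 1 (0.235) or 2 (0.0816), or flbD::Tn replicate 1 (0.131) or 2 (0.114), or with a replicate block (0.0651).

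Polarity genes showed 4 rises among 13, the same count adjusted over the list alone, with a median of -0.02, a mean of 0.32 and a test pointing up (camera adjusted p = 0.109, or 0.0273 without wild type replicate 2). The 4 were pflI (1.82), cpaM (1.04), pleA (0.93) and spmX (0.79). Of these, pflI and spmX were not called without wild type replicate 2 (adjusted p = 0.124 and 0.105) or flbD::Tn replicate 2 (0.0695 and 0.0521). The rise of pleA ended without wild type replicate 2 (0.473), flbD::Tn replicate 1 (0.18) or flbD::Tn replicate 2 (0.2). It also ended with DESeq2 (0.103), limma-voom (0.0671), DESeq2-style size factors (0.0562), library totals only (0.0596), a stricter filter (0.0515) or a replicate block (0.11). The gene tipF stayed at -0.02 (adjusted p = 0.986). Swarmer phase genes had 1 rise (pleA) and 4 falls among 14, also adjusted over the list alone (median -0.03, mean -0.88, camera adjusted p = 0.0135, and adjusted p = 0.269 with an estimated correlation). The falls were fljK, fljL, sciP and perP (-0.69, adjusted p = 0.0494), the last named after its values were seen. The fall of perP was not called without wild type replicate 1 (0.295) or 2 (0.204) or flbD::Tn replicate 1 (0.391), and the list did not pass without wild type replicate 1 (adjusted p = 0.0601, median -0.01). Its median was -0.15 without flbD::Tn replicate 1. The falls numbered 2 without wild type replicate 1 or 2 or flbD::Tn replicate 1.

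In the SOS and DNA repair list 3 of 13 rose and none fell, or 4 adjusted over the list alone (median 0.33, camera adjusted p = 0.0135, and adjusted p = 0.215 with an estimated correlation). The list did not pass without flbD::Tn replicate 1 (adjusted p = 0.0688), where its median was 0.02. Without that library or either wild type library 1 gene rose. The error-prone repair gene imuA rose from 6.09 ± 2.97 to 34.9 ± 5.13 CPM (SD, n = 2), by 2.56 (SE 0.40, adjusted p = 0.000256). Its partner dnaE2 (1.31, adjusted p = 0.00368) was not called without wild type replicate 1 (0.0719) or 2 (0.0617) or flbD::Tn replicate 1 (0.106). The recombinase gene recA (0.61, adjusted p = 0.0217) was not called without wild type replicate 1 (0.251) or 2 (0.12), or flbD::Tn replicate 1 (0.138) or 2 (0.0851), or with a replicate block (0.0671). Heat shock genes had 2 rises among 13, also adjusted over the list alone (camera adjusted p = 0.0989). They were rpoH (0.81, not called without wild type replicate 2, adjusted p = 0.185) and the small heat shock gene CCNA_02341 (0.70), which was not called without wild type replicate 1 (0.0695) or 2 (0.0632) or flbD::Tn replicate 1 (0.0708).

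Among 62 TonB-dependent receptors, which carry nutrients across the outer membrane, 7 rose and 1 fell, also adjusted over the list alone (median 0.15, camera adjusted p = 0.0135, and adjusted p = 0.269 with an estimated correlation). The median was 0.25 without wild type replicate 1 and 0.08 without wild type replicate 2. The list missed the threshold without flbD::Tn replicate 2 (adjusted p = 0.0539), and its 1 fall was in CCNA_03615 (-0.52, adjusted p = 0.0493), named after its values were seen. That fall was not called without wild type replicate 1 (0.164) or 2 (0.398) or flbD::Tn replicate 1 (0.577). Examples were CCNA_01170 (2.48, adjusted p = 2.56e-06) and CCNA_02743 (2.06, adjusted p = 0.000162). CCNA_00597 had a larger change (3.01, adjusted p = 0.00327) but was not called without wild type replicate 2 (0.0671), and CCNA_00185 (1.78, adjusted p = 0.0158) was not called without wild type replicate 1 (0.253) or flbD::Tn replicate 1 (0.0551). In the respiratory list 2 of 24 fell and none rose, also adjusted over the list alone (median -0.24, or -0.10 without flbD::Tn replicate 1; camera adjusted p = 9.06e-05, and adjusted p = 0.25 with an estimated correlation). They were the terminal oxidase genes ccoN (-1.49, adjusted p = 0.00079) and cydA (-0.97, adjusted p = 0.00263, or 0.0597 without wild type replicate 1). A further 9 lists with 103 measured members had no call by edgeR, DESeq2 or limma-voom, with 8 members at an unadjusted p under 0.05. They were flagellin glycosylation, motor stators, cyclic di-GMP turnover, DNA replication, general stress, ribosomal proteins, S-layer, prophage genes and transposases, and motor stators had 1 rise adjusted over the list alone.

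Among called genes with a mean of at least 10 CPM whose libraries did not overlap, the largest rises outside the flagellar lists, with no function given in the annotation, were CCNA_01185 (3.79), CCNA_03169 (3.57, an SH3 domain protein), CCNA_03327 (3.49) and CCNA_03906 (3.28). CCNA_03906 (positions 3578916 to 3579269, plus strand) went from 238 ± 55.8 to 2312 ± 341 CPM (SD, n = 2; adjusted p = 1.13e-08). Over the 3612 genes tested, 140 were higher and 73 lower in flbD::Tn by the edgeR quasi-likelihood test, with 80 and 41 of them at a fold of at least 2. The counts dropped without wild type replicate 1 (67 and 41), wild type replicate 2 (70 and 40) or flbD::Tn replicate 1 (74 and 42). The authors' deposited p-values, adjusted here, called 184 of the 213 genes, with the same sign for 100% of the 213.

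The comparison of ΔmadA with wild type asks which transcripts follow the loss of MadA. Of 10 class III flagellar genes 9 fell, by less than in flbD::Tn, and after madA itself a riboflavin synthesis cluster had the largest falls among the named genes. Transcripts of flgE went from 932 ± 44.2 to 283 ± 3.15 CPM (SD, n = 2), a log2 fold change of -1.72 (SE 0.16, adjusted p = 5.8e-07). Those of fljK went to 380 ± 55.0 CPM (SD, n = 2), a change of -1.37 (SE 0.15, adjusted p = 4.48e-06). CCNA_00931 (positions 1006846 to 1008048, plus strand), a bifunctional enzyme of riboflavin synthesis, fell from 1414 ± 328 to 187 ± 23.4 CPM (SD, n = 2), a change of -2.92 (SE 0.18, adjusted p = 7.99e-09). Its neighbours CCNA_00929 (-2.30, adjusted p = 4.51e-06), CCNA_00930 (adjusted p = 1.01e-06), which overlaps CCNA_00931, and ribH (-2.63, adjusted p = 0.0153, or 0.0733 without wild type replicate 1) fell too.

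The class III genes that fell in ΔmadA numbered 9 of 10, or 10 adjusted over the list alone, with a median of -1.61 (camera adjusted p = 2.62e-17, and adjusted p = 0.112 with an estimated correlation). Examples were the hook-filament junction gene flgL (286 ± 5.51 to 72.3 ± 17.0 CPM, SD, n = 2, adjusted p = 2.88e-06), flgE and the ring gene flgI (-1.67). The gene flbY (-1.70, adjusted p = 0.00621) was not called without wild type replicate 2 (0.193). Of 19 class II genes 10 rose and none fell, or 16 adjusted over the list alone (median 0.67, camera adjusted p = 2.55e-13, and adjusted p = 0.08 with an estimated correlation), and 6 rose without wild type replicate 1. The largest rises were fliL (1.54, adjusted p = 1.83e-06), fliO (1.34), fliP (1.34) and flgC (1.29). In contrast to flbD::Tn, fliF had a change of 0.48 (adjusted p = 0.0567) and passed without ΔmadA replicate 2 (adjusted p = 0.00991) or with no filter (0.043). The changes of fliX (1.02, adjusted p = 0.0685, or 0.0238 without ΔmadA replicate 1) and flhA (0.36, adjusted p = 0.208) did not pass.

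Among 8 class IV genes 5 fell and 1 rose, also adjusted over the list alone (median -1.18, camera adjusted p = 1.31e-06, and adjusted p = 0.112 with an estimated correlation). The flagellin fljN fell most, from 2628 ± 193 to 573 ± 32.1 CPM (SD, n = 2; -2.20, SE 0.14, adjusted p = 4.19e-09), followed by fljO (-1.88), fljM (-1.61) and fljK. The fall of fljL (-0.99, adjusted p = 0.00661) was not called without wild type replicate 1 (0.0894) or 2 (0.0687). The rise was in fljJ (1.02, adjusted p = 0.000137), named after its values were seen. Of 2 motor stator genes motB rose (0.47, adjusted p = 0.0282), or both adjusted over the list alone. It was not called without wild type replicate 1 (0.278) or 2 (0.104) or ΔmadA replicate 1 (0.116), or with a replicate block (0.094).

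Of 17 pilus genes 8 rose in ΔmadA and none fell, or 9 and 1 adjusted over the list alone (median 0.51, camera adjusted p = 3.69e-05, and adjusted p = 0.14 with an estimated correlation). Without wild type replicate 1 the rises numbered 5. Examples were cpaF (1.39, adjusted p = 3.32e-06), cpaD (1.37) and cpaE (1.35). The pilin gene pilA had a change of -0.87 (adjusted p = 0.0651) and passed without ΔmadA replicate 1 (1.19e-05) or wild type replicate 2 (0.0243), or with a replicate block (0.0244). Of 42 chemotaxis genes 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.417), among them CCNA_00945 (-1.86), CCNA_02402 (1.26) and CCNA_03120 (-1.20). The third fall, in cleB (-1.37, adjusted p = 0.0488), was not called without wild type replicate 1 (0.156) or 2 (0.264) or ΔmadA replicate 1 (0.0623) or 2 (0.151). It also ended with DESeq2 (0.0713), limma-voom (0.054), library totals only (0.0606) or a replicate block (0.104). The holdfast list had 2 rises and 2 falls among 24, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.446), and 1 and 1 without either wild type library. The falls included hfsJ (-1.59, adjusted p = 5.8e-07) and the rises hfsA (0.79, adjusted p = 0.000924). The other rise, hfsI (0.78, adjusted p = 0.0255), was not called without wild type replicate 1 (0.315) or 2 (0.0577) or ΔmadA replicate 2 (0.2), or with a replicate block (0.0651). The other fall, stpX (-0.47, adjusted p = 0.0442), was not called when any 1 of the 6 libraries was left out (0.0583 to 0.243), with only the 4 libraries compared (0.0733) or with a replicate block (0.0975).

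Of 24 cell division genes 7 rose and none fell in ΔmadA, or 8 adjusted over the list alone (median 0.15, camera adjusted p = 0.0505, or 0.044 without wild type replicate 2). By edgeR the count was 0 without wild type replicate 1, 3 without wild type replicate 2 and 4 without ΔmadA replicate 2. The largest rise, in mraZ (1.37, adjusted p = 0.0435), was not called without wild type replicate 1 (0.339) or 2 (0.106) or ΔmadA replicate 2 (0.163). It also ended with DESeq2 (0.0731), library totals only (0.0543) or a replicate block (0.11). The DNA translocase gene ftsK (0.71, adjusted p = 0.00153), mraW (1.12, adjusted p = 0.00259) and ftsL (0.83, adjusted p = 0.0102) were not called without wild type replicate 1 (0.0743, 0.0905 and 0.23). The genes ftsZ (-0.20, adjusted p = 0.472), ftsA (0.16, adjusted p = 0.656), ftsQ (0.45, adjusted p = 0.256) and mipZ (-0.31, adjusted p = 0.279) did not pass. Neither did ctrA (0.02, adjusted p = 0.95), gcrA (0.06, adjusted p = 0.955), ccrM (-0.05, adjusted p = 0.899), dnaA (0.07, adjusted p = 0.845) or tipF (-0.45, adjusted p = 0.111). The 1 fall among 24 cell cycle regulators, also adjusted over the list alone (camera adjusted p = 0.446), was sciP (-1.25, adjusted p = 0.0221). It was not called without wild type replicate 1 (0.222) or 2 (0.0683) or ΔmadA replicate 1 (0.113), or with a replicate block (0.0574).

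Polarity genes had 2 rises among 13 in ΔmadA, or 3 and 2 falls adjusted over the list alone, with a median of -0.23, a mean of 0.10 and a test pointing down (camera adjusted p = 0.834). They were cpaM (1.06, adjusted p = 0.000345) and pleA (1.07, adjusted p = 0.016, or 0.212 without wild type replicate 2 and 0.0502 with a replicate block). Swarmer phase genes had 1 rise and 4 falls among 14, or 1 and 7 adjusted over the list alone (median -0.33, camera adjusted p = 0.00216, and adjusted p = 0.245 with an estimated correlation). The rise was pleA and the falls were fljK, perP (-1.34, adjusted p = 0.000257), sciP and fljL. SOS and repair genes had 3 rises among 13, also adjusted over the list alone (median 0.38, camera adjusted p = 0.0226, and adjusted p = 0.245 with an estimated correlation). The list did not pass without ΔmadA replicate 2 (adjusted p = 0.0594, median 0.23) or wild type replicate 2 (0.0636), and its median was 0.63 without wild type replicate 1. The rises were imuA (2.56, adjusted p = 0.000215), dnaE2 (1.64, adjusted p = 0.000313) and recA (0.77, adjusted p = 0.0025, or 0.0737 without wild type replicate 1).

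Among 62 TonB-dependent receptors 9 rose and none fell in ΔmadA, or 12 adjusted over the list alone (camera adjusted p = 0.0899, or 0.0239 without ΔmadA replicate 2), and 3 rose without wild type replicate 1. Examples were CCNA_01170 (2.33, adjusted p = 5.8e-06) and CCNA_00224 (1.83, adjusted p = 5.61e-06). CCNA_00185 (2.06, adjusted p = 0.00389) was not called without wild type replicate 1 (0.0851). CCNA_00597 (2.25, adjusted p = 0.0306) was not called without wild type replicate 1 (0.132) or 2 (0.196) or ΔmadA replicate 1 (0.19). Its call also ended with limma-voom (0.0882), only the 4 libraries compared (0.0617) or a replicate block (0.0601). In the respiratory list 3 of 24 rose, also adjusted over the list alone, while the median was -0.13 (camera adjusted p = 0.378). They were ccoN (1.26, adjusted p = 0.00103), cydD (1.03, adjusted p = 0.0081) and cydA (0.77, adjusted p = 0.00865). The oxidase subunit gene ccoO, named after its values were seen, had a change in the other direction (-0.89) that did not pass. Without wild type replicate 1 or 2 neither cydD (0.0753 and 0.108) nor cydA (0.073 and 0.124) was called, and the same held for cydD without ΔmadA replicate 1 (0.0705) and for cydA without ΔmadA replicate 2 (0.0725). Heat shock genes had 2 rises among 13, also adjusted over the list alone (camera adjusted p = 0.34). They were rpoH (0.67, adjusted p = 0.0174, not called without wild type replicate 2, 0.273, or ΔmadA replicate 2, 0.113, or with a replicate block, 0.0756) and CCNA_02341 (0.56, adjusted p = 0.0183). The latter was not called without wild type replicate 1 (0.156) or 2 (0.129) or ΔmadA replicate 1 (0.0535), or with a replicate block (0.0521).

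Of 54 ribosomal protein genes 1 rose in ΔmadA, and 0 adjusted over the list alone (median 0.07, camera adjusted p = 0.158), while 4 and 3 rose without ΔmadA replicate 1 and 2. It was CCNA_01097 (0.61, adjusted p = 0.0174), not called without wild type replicate 1 (0.252) or 2 (0.0641) or ΔmadA replicate 2 (0.203), or with a replicate block (0.063). Flagellin glycosylation, cyclic di-GMP turnover, DNA replication, general stress, S-layer, prophage genes and transposases, 7 lists with 47 measured members, had 0 calls by edgeR, DESeq2 and limma-voom, with 7 members at an unadjusted p under 0.05. Flagellin glycosylation had 1 rise adjusted over the list alone. Among called genes with a mean of at least 10 CPM whose libraries did not overlap, the largest rises were again in CCNA_01185 (4.66), CCNA_03906 (4.08, to 4026 ± 885 CPM, SD, n = 2), CCNA_03327 (4.03) and CCNA_03169 (3.94). Over all genes tested, 188 were higher and 92 lower by the edgeR quasi-likelihood test, with 114 and 53 at a fold of at least 2. The counts dropped without wild type replicate 1 (92 and 49) or 2 (118 and 60). The authors' deposited p-values, adjusted here, called 254 of the 280 genes.

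**Figure D2:**
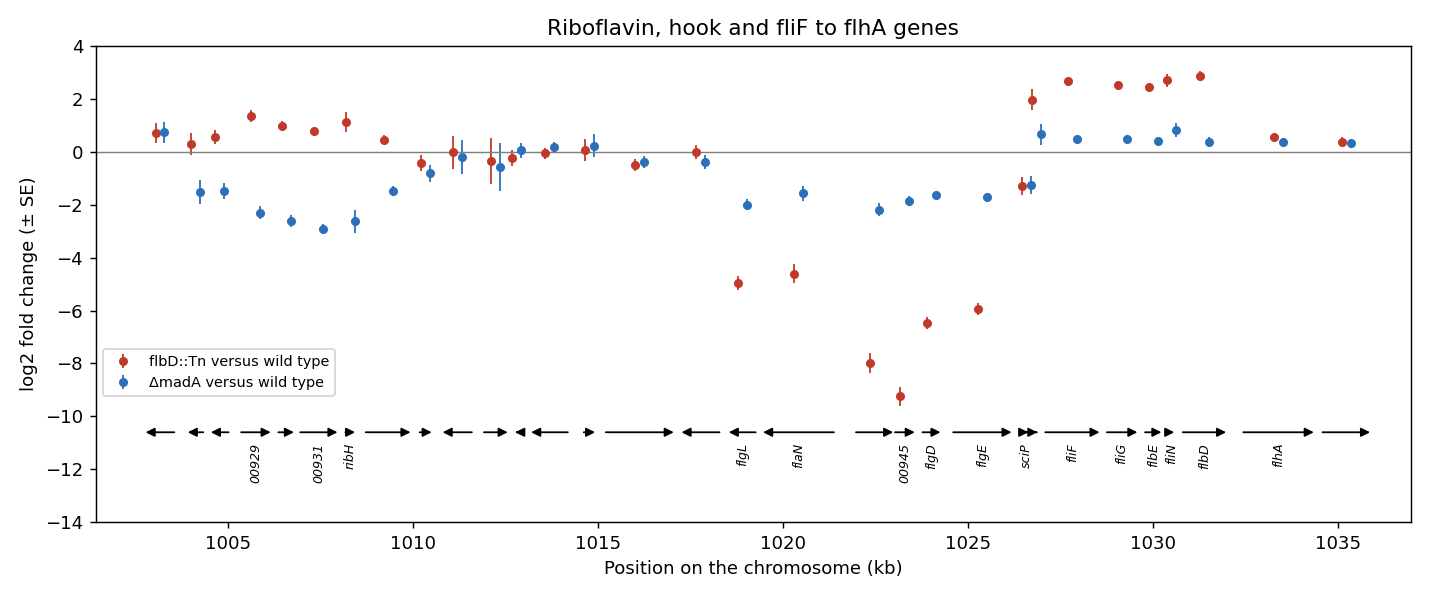
Log2 fold change against wild type, with the SE implied by the F statistic, for each tested gene of a stretch of the chromosome. The stretch holds the riboflavin genes, the hook genes and the genes from fliF to flhA, with arrows for gene direction. In flbD::Tn flgE lay at -5.95 and fliF at 2.66, whereas in ΔmadA CCNA_00931 lay at -2.92 and flgE at -1.72, and the point of CCNA_00945 in flbD::Tn rests on 3 reads.

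The direct comparison of ΔmadA with flbD::Tn, whose fold changes do not use the wild type libraries, tests where the mutants differ. Class III genes were higher in ΔmadA, the riboflavin cluster was lower, and the terminal oxidase genes ccoN and cydA were higher. The log2 fold change of flgE was 4.23 (SE 0.21, n = 2 per group, adjusted p = 1.89e-11), that of fljK 5.61 (SE 0.22, adjusted p = 5.73e-13) and that of fliF -2.18 (SE 0.16, adjusted p = 5.91e-09). CCNA_00931 stood at 187 ± 23.4 CPM in ΔmadA and 2407 ± 321 CPM in flbD::Tn (SD, n = 2), a change of -3.69 (SE 0.19, adjusted p = 1.64e-10). The terminal oxidase gene ccoN stood at 151 ± 36.1 against 22.5 ± 6.28 CPM (SD, n = 2; 2.75, adjusted p = 2.91e-07), and cydA differed by 1.74 (adjusted p = 3.12e-06).

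All 10 class III genes were higher in ΔmadA than in flbD::Tn, also adjusted over the list alone (median 3.48, camera adjusted p = 4.55e-29, and adjusted p = 0.143 with an estimated correlation). Of 19 class II genes 5 were lower, also adjusted over the list alone (median -0.09, mean -0.54, camera adjusted p = 1.1e-05, and adjusted p = 0.143 with an estimated correlation). They were flbD (-2.48), fliF, fliG (-2.03), flbE (-2.02) and fliN (-1.87), the last named after its values were seen, which lie side by side. Class IV genes had 2 higher and 2 lower among 8, or 2 and 3 adjusted over the list alone, with a median of -0.18, a mean of 0.77 and a test pointing down (camera adjusted p = 0.945). The higher ones were fljK and fljL (3.34) and the lower ones fljM (-0.73, adjusted p = 0.0025) and fljO (-1.28, adjusted p = 0.0209), with fljO not called without flbD::Tn replicate 2 (0.191) or ΔmadA replicate 1 (0.0986), or with only the 4 libraries compared (0.0528). The 1 call among 42 chemotaxis genes, also adjusted over the list alone (camera adjusted p = 0.877), was CCNA_00945. It held 550 reads in ΔmadA against 3 in flbD::Tn, a ratio of 186 with a counting interval from 63.5 to 907.

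In the respiratory list 3 of 24 were higher in ΔmadA than in flbD::Tn, also adjusted over the list alone (median 0.01, camera adjusted p = 0.0431, and adjusted p = 0.788 with an estimated correlation). They were ccoN, cydA and cydD (1.40, adjusted p = 0.00126). The gene ccoO, for another oxidase subunit and named after its values were seen, did not pass (0.22, adjusted p = 0.951). The list call ended without flbD::Tn replicate 1 (adjusted p = 0.792, median -0.06) or ΔmadA replicate 1 (0.322), or with a replicate block (0.0713). The only call among 62 TonB-dependent receptors, also adjusted over the list alone, was CCNA_02743 (-2.09, adjusted p = 0.000214; list camera adjusted p = 0.877). Polarity genes had 1 lower member among 13, also adjusted over the list alone, spmX (-0.62, adjusted p = 0.0398), which was not called without wild type replicate 1 (0.0799) or 2 (0.0722), flbD::Tn replicate 1 (0.0535) or 2 (0.459), or ΔmadA replicate 2 (0.284), with only the 4 libraries compared (0.0773) or with a replicate block (0.162). The polarity list had a median of -0.20 (camera adjusted p = 0.015, and adjusted p = 0.335 with an estimated correlation). That call ended without flbD::Tn replicate 2 (0.173) or ΔmadA replicate 2 (0.1, median -0.12).

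Swarmer phase genes had 2 higher (fljK and fljL) and 1 lower among 14, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.945). The lower one, and the only cell cycle regulator of 24 that passed (also adjusted over the list alone, camera adjusted p = 0.877), was mucR1 (-0.69, adjusted p = 0.0261). It was not called without wild type replicate 1 (0.0505), flbD::Tn replicate 1 (0.155) or 2 (0.144), or ΔmadA replicate 2 (0.211), with only the 4 libraries compared (0.0528) or with a replicate block (0.0742). Of 54 ribosomal protein genes CCNA_01440 was higher (0.58, adjusted p = 0.0299), but not without flbD::Tn replicate 1 (0.113) or 2 (0.285) or ΔmadA replicate 2 (0.2), or with a replicate block (0.161). That list also had 1 call adjusted over the list alone (camera adjusted p = 0.223, or 0.0258 without flbD::Tn replicate 2). The 17 pilus genes gave 0 calls by edgeR, with a median of 0.24 (camera adjusted p = 0.0123, and adjusted p = 0.335 with an estimated correlation), and this list call ended without flbD::Tn replicate 1 (0.0676) or ΔmadA replicate 1 (0.393, median 0.14). Together with flagellin glycosylation, motor stators, holdfast, cell division, cyclic di-GMP turnover, DNA replication, SOS, heat shock, general stress, S-layer, prophage genes and transposases, 13 lists with 140 members had no call by edgeR. At an unadjusted p under 0.05 there were 14, and DESeq2 called 2 and limma-voom 1. Adjusted over the list alone, 1 pilus gene and 2 holdfast genes were higher and 1 general stress gene was lower.

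None of fliX (-0.03), flhA (-0.20), ftsZ (-0.20), ftsA (0.10), ftsQ (0.17), mipZ (-0.31), tipF (-0.43), ctrA (-0.19), sciP (0.05), gcrA (0.23), ccrM (0.40) or dnaA (-0.19) passed between the mutants, with adjusted p from 0.227 to 0.987. The change of pilA (-0.65, adjusted p = 0.412) passed without ΔmadA replicate 1 (0.000353). Over all genes 46 were higher and 26 lower in ΔmadA by the edgeR quasi-likelihood test, and the lower count was 43 without ΔmadA replicate 1.

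The mutants shared many changes against wild type. In both, 111 genes were higher and 44 lower, so that 155 were called in the same direction. Independent lists would share 9.15 by chance. In 100 simulated data sets without an effect, with the wild type libraries shared, the mean was 0.1 and the highest 1. Neither value combines mutant effects with shared wild type noise, so the part of the 155 owed to the shared libraries was not measured. Shared rises included CCNA_03906, imuA, cpaD and CCNA_01170, and shared falls included flgE, fljK and hfsJ. A further 8 genes were called with opposite signs, madA, cydA, ccoN, CCNA_00929, CCNA_00930 and CCNA_00931 among them, with CCNA_01466 and the regulator gene ftrB, both named after their values were seen. The fall of ftrB in flbD::Tn (-0.95, adjusted p = 0.0497) was not called without wild type replicate 1 (0.275) or 2 (0.207) or flbD::Tn replicate 1 (0.483), nor was that of cydA without wild type replicate 1 (0.0597). CCNA_01466 had 0 reads in flbD::Tn against 23 in wild type and 92 in ΔmadA, at least 8.03-fold lower than wild type against a floor of 3 reads over the group. The covariance of the log2 fold changes across genes was 0.259, against 0.0545 to 0.078 in the simulations, and r was 0.596 against 0.448 to 0.569. The simulations used 2 shared wild type libraries and the fitted spread, so they bound the shared part only if that spread is right. The shared count was 84 without wild type replicate 1, 89 without wild type replicate 2 and 93 without flbD::Tn replicate 1, and the covariance was 0.444 and 0.431 without wild type replicates 1 and 2. When a mutant library was left out instead, the covariance was 0.264 to 0.288. The shared wild type part may therefore exceed the simulated range, and no simulation was run with 1 wild type library. Separate controls would leave 1 wild type library per mutant, and that comparison was not run.

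**Figure D3:**
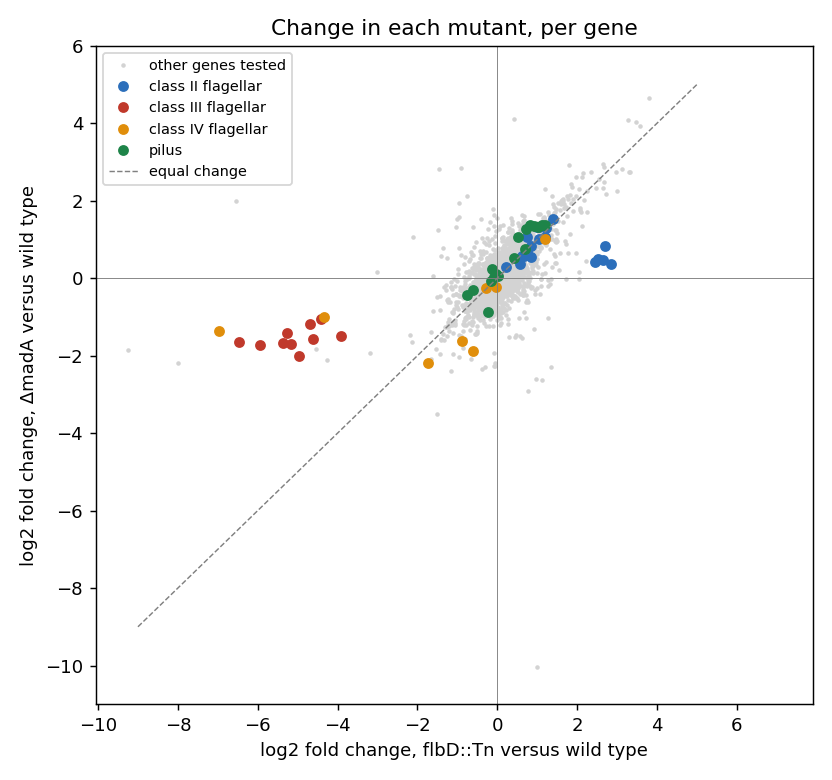
Log2 fold change against wild type in ΔmadA (vertical axis) and flbD::Tn (horizontal axis) for the 3612 genes tested, each point a gene, with flagellar classes and pilus genes in colour and a dashed line at equal change. The vertical axis ends below the largest called rise in ΔmadA (6.86), so that point is not shown. The class III genes lay between -6.47 and -3.90 in flbD::Tn and around a median of -1.61 in ΔmadA, while class II and pilus genes lay above 0 in the median of both mutants.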

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

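No call of a named gene or list reversed its direction under the alternatives run. With DESeq2, limma-voom, DESeq2-style size factors, library totals only, a stricter filter or only the 4 libraries compared, every count of calls stayed within 1.5 times its value. DESeq2 shared 187 of the 213 calls of flbD::Tn, 254 of the 280 of ΔmadA and 71 of the 72 between the mutants, each with the same sign, and the scaling choices moved the median gene by -0.026 to 0.019 on the log2 scale. Without a filter the covariance of the mutants' changes was 0.43, and the cause was not tested. A fold of at least 2, which removes small changes by construction, left 80 higher and 41 lower genes in flbD::Tn, 114 and 53 in ΔmadA and 93 shared in direction.

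A replicate block left 91 higher and 48 lower genes in flbD::Tn and 101 shared; the block takes up residual degrees of freedom, but the cause was not tested beyond that. Replicate 1 did not deviate alike across groups (r across genes of -0.037 for wild type and flbD::Tn, 0.109 for wild type and ΔmadA, -0.185 for the mutants). With ΔmadA replicate 1 set beside flbD::Tn replicate 2 and the reverse, a pairing chosen after seeing the data, 52 genes were higher and 30 lower in ΔmadA than in flbD::Tn, against 34 and 18 with the numbers as given.

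Leaving out each library in turn leaves a group with 1 sample, which is then assumed to vary like the other groups. Higher genes ranged from 67 to 177 and lower genes from 40 to 97 in flbD::Tn, from 92 to 221 and from 49 to 122 in ΔmadA, and from 34 to 69 and from 19 to 43 between the mutants. The genes shared in direction ranged from 84 to 165 and the covariance from 0.264 to 0.444. The lowest counts against wild type came with fewer libraries in the groups compared, and the highest came without a ΔmadA library, for which the cause was not tested.

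Of 182 results for named genes, DESeq2 ended 4 calls and added 1, limma-voom ended 3, library totals ended 3, DESeq2-style size factors ended 2 and added 1, the stricter filter ended 2 and added 1, no filter ended 1 and added 1, the 4 libraries compared ended 5 and added 1, and the block ended 20 and added 1. Without wild type replicate 1 or 2, 36 and 30 calls ended, against 8 to 14 for each mutant library. Of 66 list results the test with an estimated correlation ended 19 calls, the block 1 and DESeq2-style size factors none. In flbD::Tn the class III and class IV lists both lost their call in that test. The estimate was above the preset for class III (0.272) but negative, so below the preset, for class IV (-0.059). A higher correlation between genes therefore does not account for every ended call, and the cause was not tested. Depth limits low genes, since 3 reads equal 1.02 to 1.55 CPM, and changes of 1 on the log2 scale were recovered for 65% to 66% of simulated genes.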

Other observations

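The words and genes of the following descriptions, and every test below, were chosen after the results were seen. Of 40 tested genes whose product names a c-type cytochrome, heme or a heme precursor, 11 were higher and 1 lower in ΔmadA than in wild type by the edgeR quasi-likelihood test, with 5 higher without wild type replicate 1. The rest did not pass, the median log2 fold change of the 40 was 0.22, and they were not tested as a set. Against flbD::Tn 10 were higher, and 5 without flbD::Tn replicate 1. The gene hemA (positions 1534788 to 1536014, plus strand), for the first step of heme synthesis, stood at 6614 ± 348 CPM in ΔmadA against 2595 ± 666 in wild type (SD, n = 2), a log2 fold change of 1.35 (SE 0.16, adjusted p = 1.95e-05). Its change in flbD::Tn was -0.07 (adjusted p = 0.912). Of the 40 genes, 1 was lower and 0 were higher in flbD::Tn than in wild type, with a median of -0.09. The lower one was hemN (-3.01 in flbD::Tn, 0.15 in ΔmadA), so its difference between the mutants was mainly a fall in flbD::Tn. The cytochrome gene CCNA_01767 rose by 1.55 in ΔmadA (adjusted p = 0.00234). The low-oxygen regulator genes ftrB (1.94, adjusted p = 2.06e-05) and fixT (2.11, adjusted p = 0.001), and nstA, annotated as a redox regulator of the cell cycle (1.55, adjusted p = 3.43e-06), also rose. Against flbD::Tn the differences were 2.89 for ftrB (adjusted p = 2.47e-07), 2.87 for fixT (adjusted p = 0.000152) and 1.20 for nstA (adjusted p = 0.000108).

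The genes of this paragraph were named one by one after their values were seen and were not tested as a set. CCNA_02930, a very short patch repair endonuclease gene, rose by 1.74 in flbD::Tn (adjusted p = 6.73e-06) and 2.13 in ΔmadA (adjusted p = 5.8e-07). CCNA_02355, for endonuclease III, rose by 1.85 in flbD::Tn (adjusted p = 0.0023, or 0.0567 without wild type replicate 2 and 0.0528 without flbD::Tn replicate 1) and 1.94 in ΔmadA (adjusted p = 0.00111).

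CCNA_00433, named after its values were seen, had 0 reads in both wild type libraries, 34 in flbD::Tn and 29 in ΔmadA, at least 10.8-fold and at least 9.39-fold higher against a floor of 3 reads over the group.

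The riboflavin genes CCNA_00929, CCNA_00930, CCNA_00931 and ribH fell in ΔmadA. In flbD::Tn CCNA_00929, CCNA_00930 and CCNA_00931 were called higher than in wild type, and ribH was not, so the direct difference between the mutants holds both shifts. Loss of the cluster from the strain is argued against by the reads left, with a lowest count of 36 in any ΔmadA library for the 4 genes. A single odd library is argued against as well, since both ΔmadA libraries lay below every other library, by at least 1.78 on the log2 CPM scale. A second change carried by the ΔmadA strain or its cultures stays open, because both cultures carry the same strain, and it may account for the median fall of -2.62 as well as the loss of MadA could. An independent ΔmadA strain or a complemented one would be needed and was not analysed here.

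Of 19 class II genes 16 rose in flbD::Tn, those from fliF to flbD most. Transcription out of the transposon is argued against for the class, as the 14 genes outside the fliF to flbD stretch had a median of 0.85 (bootstrap interval 0.69 to 1.06). Read-out along the operon is argued against for the genes ahead of flbD. Of these fliF, the farthest ahead, rose by 2.66 (interval from its SE, 2.34 to 2.97). For flbD minus fliF the value was 0.2 (interval from their SEs, -0.29 to 0.68). Neither the insertion site nor the strand setting is known, so transcription from the transposon against the operon, counted without strand, stays open. Loss of repression by FlbD is a candidate explanation that no test here separates from that one.

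The mutants shared rises outside the flagellum, and one hypothesis is that ΔmadA may be a uniformly weaker form of flbD::Tn, as class III genes kept a median share of 0.3 of their fall (bootstrap interval 0.25 to 0.36). That was weighed by the direct difference between the mutants over the 118 genes called higher in flbD::Tn outside the flagellar lists. Its median was 0.07 (bootstrap interval 0 to 0.13), and -0.01 to 0.11 with any 1 library left out. A share of 0.3 would need -0.78. Of the genes, 6 were lower and 1 was higher in ΔmadA. The difference uses no wild type library, but the choice of the 118 genes and the value of -0.78 do. Rises owed to low wild type reads would also leave a difference near 0. The values therefore argue against a uniformly weaker form only for rises not owed to the wild type libraries. A growth difference of the wild type cultures, which both comparisons share, stays open as a cause of the rises, since a median of 0.07 for ribosomal protein genes in ΔmadA, and of 0.01 in flbD::Tn, does not decide it. Genes are not independent, so the intervals are likely too narrow.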
